A study of Mus musculus with 12 samples.

How the data were processed

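The data were 12 arrays of mouse fetal gonadal somatic cells at embryonic day 11.5, with 3 embryos in each of 4 groups made from sex and Kdm3a genotype. Per the labels' protocols, about 200000 cells were dissociated from the gonads and mesonephroi of an embryo, about 40000 were purified through the CD271 transgene, and the RNA was amplified linearly and labelled with Cy3. Each label names a single embryo; litters are not given in the sources used here. The submitters' processing notes name Agilent Feature Extraction. Per the file headers, its version was 10.5.1.1 and the array design 014868, built on the mm9 assembly. Per the file headers, the deposited intensity is a processed signal, background-subtracted on a linear scale and not scaled between arrays; the raw median signal and local background are deposited as intensities too.

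From these, log2 of the processed signal minus the 75th percentile of the array was computed. Of 45018 spots 43379 were not controls, spots marked as outliers by the software were left out, and the 245 probes with 10 spots each were averaged, which left 41174 probes. The arrays name probes by accession; 27479 probes matched 18749 symbols through a RefSeq table of GRCm38.p6, used for names and neighbours alone, and 13695 kept the accession of the array. A probe was tested where it was well above background on all arrays of at least 1 group, and the probe with the highest mean stood for its gene, which gave 19178 features, 13264 of them named genes. Other probes of called genes went the opposite way in 1 case in males and 1 case in the control sex comparison.

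Group means were fitted over all 12 arrays in limma 3.58.1 under R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment at 0.05. The 5 contrasts were the mutant effect in each sex, the sex difference in each genotype and the difference of the mutant effects. The p-values rest on the spread between single embryos within groups, pooled over the 4 groups, and do not account for slide. In a group not well above background, that spread is of the background signal and not of expression. Sry is such a gene, with an SD of 0.43 in control males and 0.0727 in mutant females. For such genes the p-values and standard errors rest partly on arrays at background. The 19 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with adjustment over the 19 lists of a contrast and an estimated correlation as an alternative. Where a probe was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal.

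Genes were named by a rule fixed before the data were examined: Kdm3a, Sry and Sox9; up to 6 largest rises and 6 largest falls past the threshold with groups that did not overlap, leaving out clone names and accessions; and the 3 members of each list with the smallest p. Some genes that this rule names are not reported here. The arrays lay on 3 slides of 4, each scanned once, so slide and scan were 1 batch. Slide 1 held the control males and mutant male 1, slide 2 mutant males 2 and 3 with control females 1 and 2, and slide 3 control female 3 with the mutant females.

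Alternatives were quantile normalization, normexp background correction, other filters on dim probes, every probe tested separately, only the groups compared, array weights, the replicate number or the slide as a block, an added fold threshold, and leaving out each array. The brightness of the array as a covariate was added after the data were examined. Normexp used the median signal with an offset of 50, since the files hold no mean signal of the spot. With the local backgrounds as deposited its fit broke down on mutant male 2, where 4 spots had a local background far above their signal, up to 49723 against a median of 27. The fitted background of that array was -325.7, and the median corrected signal was 449.3. Local backgrounds that the software marked as outliers were therefore replaced by the median of the array, which gave -4.49 and 77.0. This rule was chosen after the data were examined, from the fitted backgrounds and not from the calls.

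The fit was tested on simulated data for the mutant effect in males over 19178 features, with 50 features changed at each size. It recovered 3 at 1.5-fold, 26 at 2-fold, 44 at 4-fold and 49 at 8-fold, with 9 false calls. Among the features left unchanged there, 0 were called for the mutant effect in females and 0 for sex in controls, and 9 for sex in mutants, a comparison that holds the changed mutant males. In a simulation of 19 lists of which 1 was shifted, camera called the shifted list and 1 other. The simulated noise was independent between features, without the slide or brightness structure of these arrays, so these false calls do not carry over to them. Figures were drawn with matplotlib.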

Results

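Gene expression was measured in the somatic cells of the fetal mouse gonad at embryonic day 11.5, the stage at which Sry, the Y-linked gene that starts testis development, is active. Embryos were either heterozygous (controls) or homozygous (mutants) for a mutant allele of Jmjd1a, here called by its current symbol Kdm3a, which encodes a demethylase of histone H3 lysine 9. The cells were purified from the gonads and mesonephroi of single embryos through a CD271 transgene driven by Nr5a1, a gene of gonadal somatic cells. Each of the 12 arrays held the RNA of 1 embryo, in 4 groups of 3: control females, mutant females, control males and mutant males. On the 12 arrays, 58.0% to 65.2% of the spots were well above background, and the 75th percentile of the signal lay between 142.9 and 299.5, a 2.10-fold range. The number of arrays limits the precision of every value below. Levels are log2 values relative to the 75th percentile of the same array, changes are log2 differences with the standard error of the limma fit, and n = 3 embryos per group throughout. A fold given as "at least" sets a group well above background against one that was not, as described under the processing.

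Kdm3a, the targeted gene, separated the mutant from the control arrays. Its representative probe stood at 2.86 ± 0.165 (SD) in control males and 0.91 ± 0.183 in mutant males, 3.86-fold lower in the mutants (limma adjusted p = 9.0e-05). In females it stood at 2.90 ± 0.0735 in controls and 0.62 ± 0.165 in mutants, 4.84-fold lower (limma adjusted p = 4.2e-05). The second Kdm3a probe was well above background on all control arrays and on no mutant array, at least 4.07-fold lower in mutant males and at least 6.07-fold lower in mutant females. Whether either probe lies in the part of the gene that the mutation removes is not given in the sources used here, and a probe outside that part would not check the genotype. Within slides, the representative probe differed by -1.82 in males (1 mutant against 3 control arrays) and by -2.34 in females (3 mutant arrays against 1 control array). Xist, transcribed from the inactive X, was at least 769-fold lower in control males than in control females, and Ddx3y, a Y-linked gene, at least 74.0-fold higher, so the sex labels matched these genes.

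The first comparison asked what the loss of Kdm3a changed in male gonadal cells at the stage of sex determination. Sry was well above background in all 3 control males and in none of the 3 mutant males, at least 2.66-fold lower (limma adjusted p = 0.0023). Sox9, the transcription factor that Sry activates, fell by 1.05 ± 0.18 (2.07-fold, limma adjusted p = 0.036), and Fgf9, a growth factor that maintains Sox9, fell by 1.14 ± 0.16 (limma adjusted p = 0.015). Cst9, a cystatin on the testis list, fell by 1.65 ± 0.28 (limma adjusted p = 0.033). In all, 90 of 19178 features passed the threshold, 15 higher and 75 lower in mutants, and the groups did not overlap in any of the 90. Chance gives this in 10% of unselected features, but the 90 were selected for their difference, so it adds no support.

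Tph2, the tryptophan hydroxylase of serotonin neurons, was at least 6.94-fold lower (limma adjusted p = 0.000815). Rnase1, a secreted ribonuclease, fell by 3.53 ± 0.35. Myl7, the atrial myosin light chain, fell by 2.81 ± 0.22, and Pnliprp2, a pancreatic lipase, fell by 2.49 ± 0.17. Vav3, a guanine nucleotide exchange factor, fell by 2.24 ± 0.13. Gpat2, an acyltransferase of the germline, rose by 2.00 ± 0.30 (4.01-fold), Lalba, a milk protein gene, by 1.78 ± 0.30 and Tspan33, a tetraspanin, by 0.98 ± 0.18. Hoxd1 was at least 2.23-fold, Slc25a31 at least 1.1-fold and Tmem270 at least 1.07-fold higher; none of these was well above background in control males, and Tmem270 was so in 2 of the 3 mutant males. Gpat2 was well above background in 2 of the 3 control males.

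The testis pathway list moved down as a group in mutant males. Of its 16 measured members 15 were lower, 4 passed the threshold over all genes (Sry, Fgf9, Cst9 and Sox9) and 9 did so adjusted over the list alone, with a median change of -0.77 (camera adjusted p = 4.5e-08). With an estimated correlation between the genes the adjusted p was 0.061. Genes of mesonephric epithelium, the tubules beside the gonad, moved up, with a median of 0.62 (camera adjusted p = 1.1e-05; adjusted p = 0.14 with an estimated correlation). None of their 12 members passed over all genes and 5 did adjusted over the list alone. The epithelial cadherin Cdh1, well above background in 1 of the 3 control males, stood at 1.71 ± 0.34, the transcription factor Gata3 at 1.01 ± 0.22 and the signal Wnt9b at 1.89 ± 0.49. Endothelial genes had a median of 0.55 (adjusted p = 0.040, and 0.64 with an estimated correlation), with Cdh5 at 1.07 ± 0.76 and Tek at 0.64 ± 0.46. The medians were 0.19 for hypoxia response genes and 0.18 for mesenchymal genes (each adjusted p = 0.043, and 0.64 with an estimated correlation). No member of these 3 lists passed. With slide as a block the medians were -0.75 for the testis pathway and 0.70 for mesonephric epithelium, and the calls of the endothelial (-0.10), hypoxia response (-0.01) and mesenchymal (0.02) lists ended. The mesenchymal call also ended with quantile normalization (0.18, adjusted p = 0.0735) and with array brightness as a covariate (0.06, adjusted p = 0.070).

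Several lists did not pass in males. The ovary pathway had a median of 0.16 (camera adjusted p = 0.27), with Lef1 at 0.44 ± 0.25 and Msx1 at 0.37 ± 0.20, and the bipotential gonad list one of 0.18 (adjusted p = 0.071), with Cbx2, a regulator of Sry, at 0.53 ± 0.25 and Lhx9 at 0.38 ± 0.22. Steroidogenic genes had a median of -0.27 (adjusted p = 0.12), and Mc2r, the corticotropin receptor, stood at -1.05 ± 0.22. Among the H3K9 demethylases (median 0.22, adjusted p = 0.44) Kdm3a alone of 11 members passed, and Kdm3b stood at 0.55 ± 0.25. The germ cell list (0.16, adjusted p = 0.12), with Ddx4 at 1.02 ± 0.34, the neural list (0.42, adjusted p = 0.14), the macrophage and leukocyte list (0.52, adjusted p = 0.14), the erythroid list (0.41, adjusted p = 0.18) and the cell cycle list (0.02, adjusted p = 0.27) did not pass either.

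The call of Sox9 was lost without any single one of 5 of the 6 male arrays, all but mutant male 3 (limma adjusted p up to 0.162), and over 12 other settings its adjusted p ranged from 0.0131 to 0.223, the highest with slide as a block at a change of -1.09. The adjusted p of Fgf9 ranged from 0.00596 to 0.11, and its call was lost without control male 1 or control male 2; the calls of Cst9 and Gpat2 were each lost without any single one of 4 arrays. For Sry it ranged from 0.000207 to 0.483, the highest with normexp background correction, which compresses dim signals (-0.40), and no left-out array ended the call. Where every probe was tested separately, these ranges take the probe of a gene with the smallest p. The second Fgf9 probe, well above background on all 12 arrays, stood at -0.90 and was not called (limma adjusted p = 0.134). A Sox9 probe at -1.305 was not called either (limma adjusted p = 0.214). The count of 90 was 52 (7 higher, 45 lower) with slide as a block, and 26 of the 52 were among the 90. The number of higher features, 15, was 4 with normexp, 0 without a filter on dim probes, 0 without control male 1 and 1 without mutant male 2 or mutant male 3. The whole count was 25 without control male 1, 40 without control male 2, 34 without mutant male 3, 48 without mutant male 2 and 52 without mutant male 1.

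**Figure D1:**
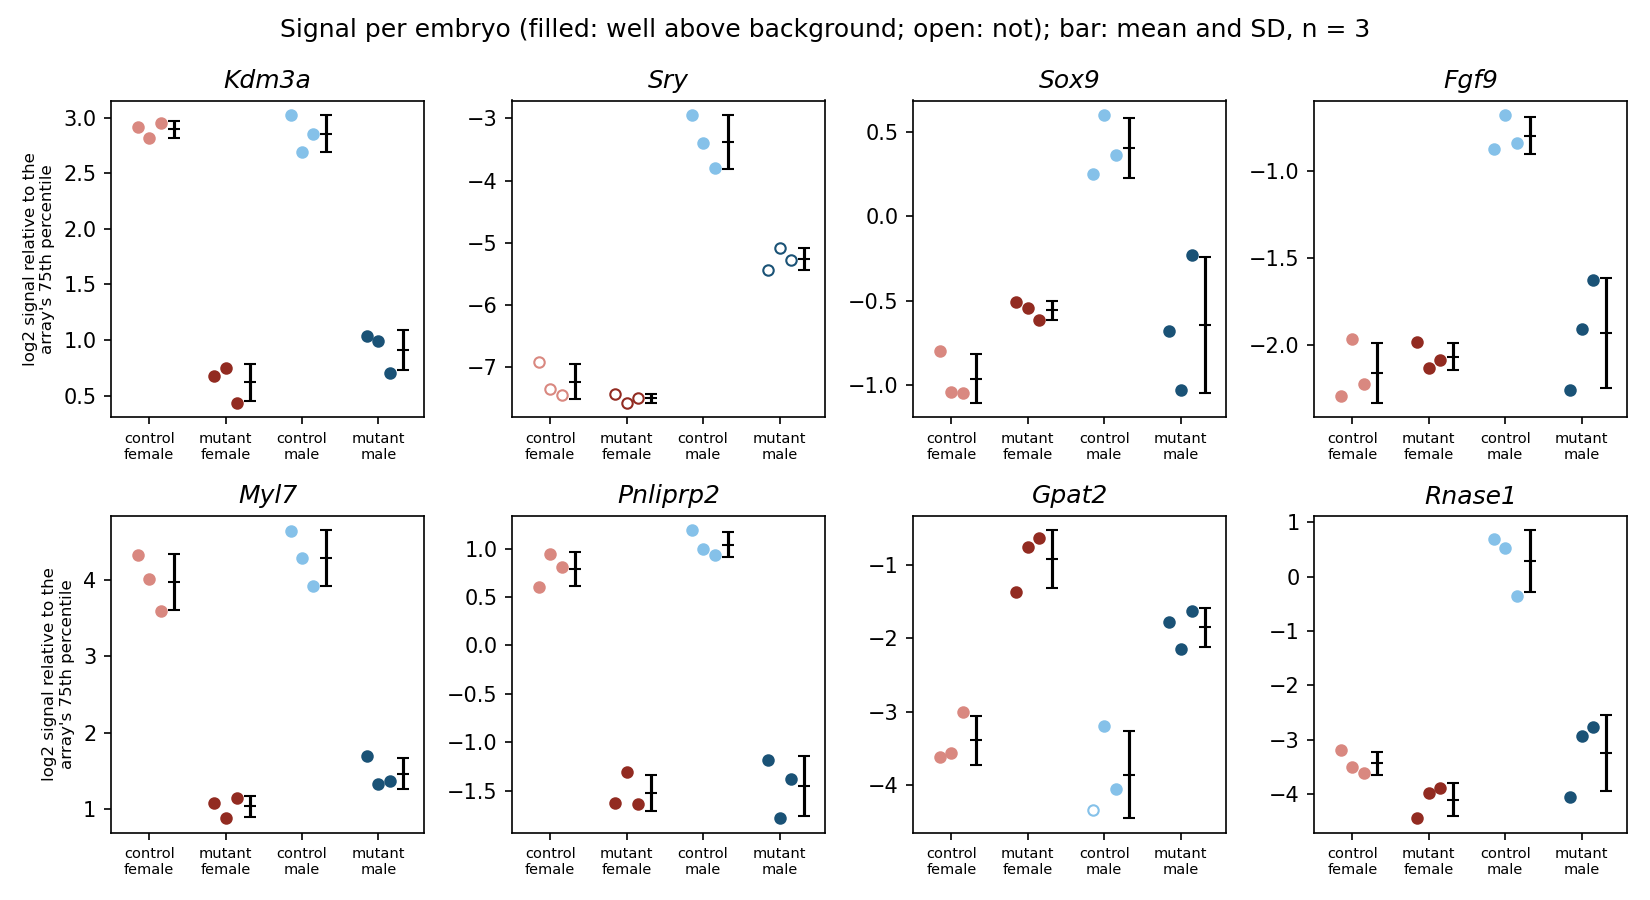
Signal of 8 genes in each embryo, as log2 relative to the 75th percentile of the array (y axis), by group (x axis); filled points are well above background, open points are not, and bars give the mean and SD of 3 embryos. Sry was well above background in the 3 control males alone, and Kdm3a was lower in all 6 mutants than in all 6 controls.

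In females the comparison asked which of these changes occur without Sry. Gpat2 rose by 2.47 ± 0.30 (5.54-fold, limma adjusted p = 0.0050) and was the only feature of 68 past the threshold that was higher in mutants, while 67 were lower. Tph2 was at least 7.87-fold lower, and Ugt2b36, a glucuronosyltransferase, at least 1.99-fold lower. Myl7 fell by 2.93 ± 0.22, Smtnl1, a smoothelin-like muscle protein that was well above background in 2 of the 3 mutants, by 2.45 ± 0.25, Sprr2d, an epidermal protein, by 2.49 ± 0.36 and Ccdc182 by 2.44 ± 0.28. Sox9 stood at 0.41 ± 0.18 (limma adjusted p = 0.48) and Fgf9 at 0.09 ± 0.16 (limma adjusted p = 0.77). Cst9 was not called, but its levels were 1.681, 1.947 and 1.275 in control females and 0.467, 1.182 and 0.868 in mutant females. Of the 16 measured testis pathway members 9 were higher and 7 lower in mutant females, and 1 of the lower ones passed adjusted over the list alone.

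The genes that fell in females were largely those that fell in males. Of 75 and 67 falling features 40 were shared, where independent lists would share 0.262 (Fisher's exact test, one-sided, p = 4.8e-84). The comparisons share no array, but both take the spread of each feature from the same fit over all groups. Features with a small spread are thus favoured in both lists, and features are not independent of each other. Both 0.262 and the p-value assume an independence that these lists lack. How much of the overlap this accounts for was not tested. Tph2, Myl7, Smtnl1, Vav3, Pnliprp2 and Kdm3a were among the 40, and Gpat2 rose in both. Across all 19178 features, which are not independent replicates, the mutant effects of the sexes correlated with r = 0.490 (Pearson) and rho = 0.577 (Spearman). The 75th percentile of the signal was 142.9, 169.7 and 220.7 in control males and 204.9, 175.3 and 220.8 in mutant males. In females it was 188.7, 250.1 and 280.0 in controls and 299.5, 291.5 and 268.3 in mutants. What array brightness adds to these correlations was not tested. Of the 117 features called in either sex, 112 moved the same way in both, as did 14586 of all 19178 features.

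Among the lists in females, steroidogenic genes moved down with a median of -0.32 (camera adjusted p = 0.0087; adjusted p = 0.32 with an estimated correlation). None of the 10 members passed over all genes and 3 did adjusted over the list alone, namely Star, the cholesterol transporter, at -0.74 ± 0.15, Akr1b7 at -0.97 ± 0.31 and Mrap at -0.91 ± 0.30. The bipotential gonad list had a median of 0.21 (adjusted p = 0.0087, and 0.71 with an estimated correlation), mesenchymal genes one of 0.25 (adjusted p = 0.019, and 0.71) and H3K9 methyltransferases one of 0.17 (adjusted p = 0.045, and 0.71), with no member past the threshold in any of these 3. The testis pathway (0.06, adjusted p = 0.89), the ovary pathway (0.08, adjusted p = 0.89) and mesonephric epithelium (-0.11, adjusted p = 0.83) did not pass. Fst, which encodes follistatin, stood at -1.10 ± 0.34 (limma adjusted p = 0.36). The slide block left 13 features, 10 of them among the 68, and of the 4 lists only the steroidogenic one kept its call (-0.46), with the bipotential gonad median at -0.07 and Gpat2 at 2.08 but not called (adjusted p = 0.285). With array brightness as a covariate the steroidogenic list alone of the 4 kept its call too (-0.30, adjusted p = 4.0e-05), and the bipotential gonad (0.14, adjusted p = 0.104), methyltransferase (0.09, adjusted p = 0.239) and mesenchymal (0.07, adjusted p = 0.113) lists lost theirs. Quantile normalization ended the calls of the mesenchymal (adjusted p = 0.0655) and methyltransferase (adjusted p = 0.0754) lists, and the replicate block that of the methyltransferases (adjusted p = 0.0581). The count was 135 (29 higher, 106 lower) without control female 3, and 37, 31, 31, 44 and 36 without control female 1, control female 2, mutant female 1, mutant female 2 and mutant female 3.

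The comparison of control males with control females gave the sex difference that the mutants are set against. Sry was at least 2.90-fold higher in males (limma adjusted p = 5.0e-06), Sox9 was 2.59-fold higher (1.37 ± 0.18, limma adjusted p = 0.015), Fgf9 2.58-fold (1.36 ± 0.16, limma adjusted p = 0.0056) and Rnase1 13.1-fold (3.71 ± 0.35). The Y-linked genes Eif2s3y, Kdm5d and Uty were at least 69.7-fold, 29.2-fold and 3.83-fold higher. Xist and its antisense transcript Tsix were at least 769-fold and 44.2-fold lower. Lalba fell by 2.06 ± 0.30 from females to males, Trim55, a muscle ubiquitin ligase, by 1.79 ± 0.25, H2ap, an X-linked histone gene, by 1.37 ± 0.16 and the peptide receptor Adcyap1r1 by 1.23 ± 0.18. The call covered 34 features, 17 higher and 17 lower in males.

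All 16 measured testis pathway genes were higher in control males than in control females. Their median was 1.23 (camera adjusted p = 5.9e-13; adjusted p = 0.0054 with an estimated correlation), 3 passed over all genes and 9 adjusted over the list alone. The Y-linked list (median 5.26) and the list of X inactivation and escape (median -0.58) passed with either correlation (adjusted p = 8.5e-21 and 2.2e-13, and 0.0051 and 0.0047 with an estimated correlation). These medians are of fitted values that include genes not well above background in 1 sex, so they are not folds. Immediate early and heat shock genes, which respond to handling of cells, were lower in control males with a median of -0.84 (adjusted p = 2.1e-05; adjusted p = 0.55 with an estimated correlation), with 15 of 16 members lower, such as Dusp1 at -1.51 ± 0.52 and Junb at -1.24 ± 0.50. With array brightness as a covariate this median was -0.45 (adjusted p = 0.076), and with slide as a block -1.80 (adjusted p = 4.1e-08). Erythroid genes had a median of -1.01 (adjusted p = 0.014, and 0.63 with an estimated correlation; -2.19 with the brightness covariate, adjusted p = 0.030) and mesonephric epithelium one of -0.44 (adjusted p = 0.0005, and 0.19). The ovary pathway had a median of -0.27 (adjusted p = 0.057), with Fst at -0.95 ± 0.34.

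No slide held control males together with control females. The slide block, which then links the sexes through the mutants, left 13 features, 8 of them among the 34; Sox9 (1.38, adjusted p = 0.60, from 0.000702 to 0.6 over its settings) and Fgf9 (1.82, adjusted p = 0.0575) lost their calls, as did the erythroid (0.46) and mesonephric (-0.21) lists, and normexp gave Sry an adjusted p of 0.066. Sox9 also lost its call without control female 2, control female 3 or control male 2, and the count was 19 without control female 3, 20 without control female 2, 20 without control male 2 and 21 without control male 1. Where every probe was tested separately, the range of Sox9 takes its probe with the smallest p. A Sox9 probe at 1.73 (limma adjusted p = 0.117) and the second Fgf9 probe at 1.08 (limma adjusted p = 0.103) were not called.

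Between mutant males and mutant females the testis genes were closer. Sox9 differed by -0.09 ± 0.18 (limma adjusted p = 0.84) and Fgf9 by 0.14 ± 0.16 (limma adjusted p = 0.71). Sry passed the threshold (limma adjusted p = 0.00095), but it was not well above background on any array of either group, so no fold is given; its call was lost with slide as a block (adjusted p = 0.497) and with normexp (adjusted p = 0.115). The testis pathway had a median of 0.22 (camera adjusted p = 0.080). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at least 87.6-fold, 64.0-fold, 37.0-fold and 4.21-fold higher in males, and Cd99, a surface glycoprotein, was 1.66-fold higher. Xist and Tsix were at least 876-fold and 47.2-fold lower, Kcnc1, a potassium channel, at least 4.31-fold lower, and H2ap, Dcaf12l2 and Adcyap1r1 fell by 1.27 ± 0.16, 1.26 ± 0.14 and 1.26 ± 0.18. In total 25 features passed, 10 higher and 15 lower in males, and 18 differed the same way in controls.

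Immediate early genes were lower in mutant males too, with a median of -0.66 (camera adjusted p = 0.0014; adjusted p = 0.46 with an estimated correlation). Hypoxia response genes had a median of 0.31 (adjusted p = 0.0075; 0.18 with quantile normalization, adjusted p = 0.0153), imprinted genes one of -0.20 (adjusted p = 0.020) and the bipotential gonad list one of -0.22 (adjusted p = 0.041), each with an adjusted p of 0.46 with an estimated correlation. Aldoa, a glycolytic enzyme, stood at 0.53 ± 0.14 and Igf2 at -0.45 ± 0.13. The Y-linked list (median 5.80, adjusted p = 6.0e-21) and the X list (median -0.51, adjusted p = 3.8e-13) passed, each with an adjusted p of 0.0050 with an estimated correlation. With slide as a block 7 features passed, 6 of them among the 25, the bipotential gonad median was 0.26 and imprinted genes lost their call (-0.04); with array brightness as a covariate the immediate early list lost its call (-0.14, adjusted p = 0.80; with slide as a block -1.23, adjusted p = 0.0011), as did the imprinted and bipotential gonad lists. Quantile normalization ended the bipotential gonad call (adjusted p = 0.0513). The count was 11 without mutant female 1, 16 without mutant female 2, 13 without mutant female 3 and 14 without mutant male 1. On the slide with 2 mutant males and 2 control females the immediate early median was -1.04.

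The difference of the mutant effect between the sexes was tested directly. No feature passed (limma, smallest adjusted p = 0.82), and 701 had an unadjusted p under 0.05, where 959 would by chance. Sox9 differed by -1.46 ± 0.26 and Fgf9 by -1.23 ± 0.23 (each limma adjusted p = 0.82). For Sry no size is given, since it was well above background in control males alone (limma adjusted p = 0.82). As a group the testis pathway changed more in males, with a median difference of -0.85 (camera adjusted p = 1.3e-12; adjusted p = 0.016 with an estimated correlation), and 6 of its 16 members passed adjusted over the list alone. Mesonephric epithelium differed by a median of 0.63 (adjusted p = 3.7e-09; adjusted p = 0.038 with an estimated correlation), with all 12 members above 0. The slide block gave 8 features, 2 above and 6 below 0, and the brightness covariate gave 1, Sry (adjusted p = 0.017).

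**Figure D2:**
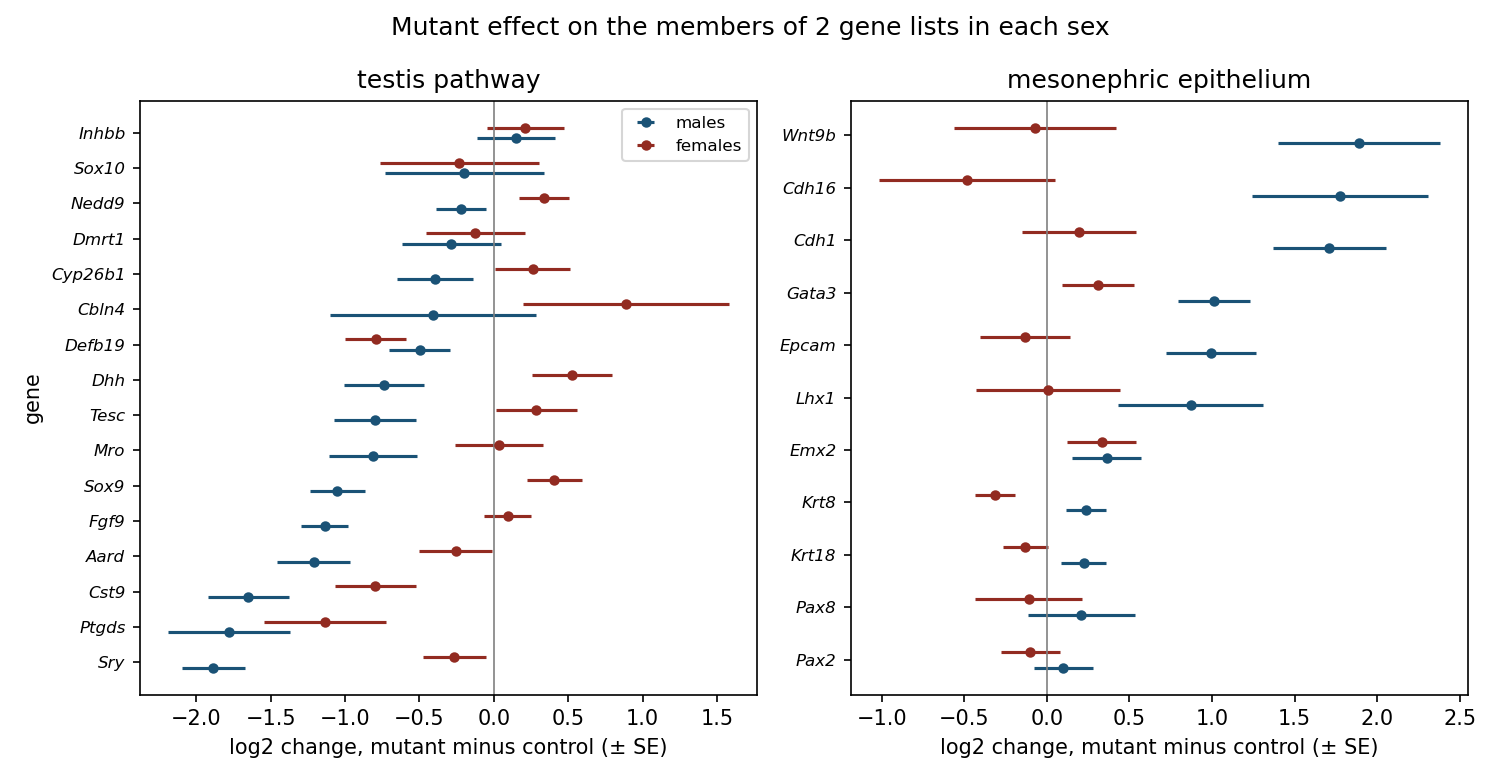
Change from control to mutant (x axis, log2, mean ± SE of the limma fit, 3 embryos per group) of the 16 measured members of the testis pathway list and 11 of the 12 of the mesonephric epithelium list (y axis), in males and in females. In males 15 of 16 testis pathway genes lay below 0, and the median of the list was -0.77 in males and 0.06 in females.

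Of the features higher in control males than in control females, 9 of 17 fell in mutant males, Sry, Sox9, Fgf9 and Rnase1 among them, where independent lists would share 0.0665. Both comparisons use the same control males and the same spread of each feature, so these lists are not independent. In 20 simulations with all 12 arrays drawn anew and no group different, the highest overlap was 0. Data without differences give hardly any calls, so this 0 does not measure what the shared controls add. With 3 control males no split left 2 arrays in each part, so part of the excess may come from the shared controls.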

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

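The tests of cell composition, the brightness covariate, slide as a block for lists and the splits for the difference of the mutant effects were chosen after the results were seen. Lists whose mutant effect differed between males and females are given here, with the difference of the medians taken as males minus females. These were the testis pathway (-0.85), endothelial genes (0.76, camera adjusted p = 0.0003; adjusted p = 0.78 with an estimated correlation; -0.08 with slide as a block), mesonephric epithelium (0.63) and hypoxia response genes (0.17, adjusted p = 0.0082; adjusted p = 0.75 with an estimated correlation and 0.168 with slide as a block).

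The fall of the testis pathway in mutant males was weighed against a lower share of gonadal cells, array brightness and slide. A loss of gonadal cells at large would lower genes of the bipotential gonad. Their list, which also holds regulators of Sry such as Map3k4 and Mapk14, had a median of 0.181 in mutant males with 14 of 18 above 0. It did not pass (camera adjusted p = 0.071, and 0.64 with an estimated correlation). The absence of a fall argues against a loss of gonadal cells at large. It says nothing about a lower share of only those gonadal cells that express the testis pathway. With brightness as a covariate the median was 1.01 times the one without, which argues against brightness. Within slide 1 the median was 0.978 times the one over all arrays, but that slide holds a single mutant male, so slide and genotype cannot be told apart for the other mutant males. On slide 2 the median of mutant males 2 and 3 over control females 1 and 2 was 0.296. Control males over control females, which shared no slide, had a median of 1.23. With no control male on slide 2, its value does not measure the mutant effect there. An effect of the genotype on the testis pathway stays open as a hypothesis.

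The rise of mesonephric epithelium genes in mutant males may come from more cells of the mesonephros and of other non-gonadal types, which the CD271 purification would remove. All 4 of the other non-gonadal lists had positive medians (endothelial 0.55, macrophage 0.52, neural 0.42, erythroid 0.41), as that would need. Within slide 1, only 1 of the 4 was positive while mesonephric epithelium stood at 0.70, so with a single mutant array there the explanations cannot be told apart. With brightness as a covariate the median was 0.898 times the one without, which argues against brightness. A change within the epithelium stays open.

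Of the 10 splits of 6 arrays, 1, the real one, gave as many features in each pairwise comparison, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 90 and 26 for the mutant effect in males, 68 and 41 in females, 34 and 1 for sex in controls, and 25 and 0 for sex in mutants. The splits with 26 and 41 features parted the 3 brightest from the 3 dimmest arrays. For the difference of the mutant effects all 100 splits gave at least the real count of 0, which any split must, so this says nothing about chance. The highest gave 8829, and it too parted the arrays of each sex by brightness, a structure of the samples other than the groups. For the mutant effect averaged over the sexes, 214 features passed (25 higher, 189 lower), 2 of 100 splits gave as many, the real one included, and the other gave 3555.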

How the results depend on the processing

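The brightness covariate, the gene-by-gene array weights, the replaced local backgrounds and slide as a block for lists were chosen after the data were examined. Quantile normalization, normexp, every probe tested separately and the fold threshold kept each count of features within 1.5 times the reported one. With normexp the counts were 64, 78, 30 and 23 (males, females, sex in controls, sex in mutants), and the median of all features stood at 0.112 and 0.121 in the sex comparisons, against 0.0395 and 0.0454 as reported. The split moved too, to 4 higher and 60 lower in males and to 18 higher and 12 lower for sex in controls. With the local backgrounds as deposited they were 10, 7, 4 and 4, from a fit that had broken down on 1 array. Without a filter on dim probes the counts were 35 in males (0 higher) and 43 in females, and with probes well above background on all 12 arrays 11 for sex in mutants. With only the groups compared, which leaves fewer arrays for the spread, they were 26, 34, 10 and 10. With slide as a block they were 52, 13, 13 and 7, and 8 for the difference of mutant effects; with the brightness covariate 54 and 42 for the mutant effects, 10 for sex in mutants and 1 for the difference. The cause was not tested.

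Array weights gave 5103, 6412, 355 and 201 features, from an estimate that did not converge, and the gene-by-gene estimate 1891, 5283, 233 and 89. Other splits of the same arrays gave up to 7630, 13352, 5713 and 3920 with the first and 5930, 9027, 733 and 555 with the second, more than the real groups, so these counts do not measure the group effects. Leaving out 1 array gave 25 to 61 features in males, 31 to 135 in females, 19 to 41 for sex in controls, 11 to 19 for sex in mutants and 0 for the difference. The replicate numbers did not pair the arrays (same-number correlations from -0.532 to 0.426; 3 of 12 arrays closest to their own number), and with the replicate block the count for sex in mutants was 16. With an estimated correlation the numbers of lists past the threshold were 0 and 0 for the mutant effects (males, females), 3 and 2 for sex (controls, mutants) and 2 for the difference, against 5, 4, 6, 6 and 4. In females 2 lists passed with quantile normalization, both among the 4, and 2 with the brightness covariate, 1 of them among the 4, and with slide as a block 2 for the difference.

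None of the 71 called values of genes named in the text changed sign under the alternatives that gave them a value; the other called features were not followed. Genes not called changed sign as follows. In mutant females Sry stood at 0.029 with quantile normalization and 0.028 with the brightness covariate, Fgf9 at -0.032 with normexp and -0.33 with every probe tested separately, and Map3k4, Mapk14 and Setdb1 at -0.0025, -0.047 and -0.0097 with slide as a block. Tek stood at -0.15 in mutant males with normexp. For sex in controls, Cdh1 stood at 0.062 with normexp, Fst at 0.18 with slide as a block and Kdm3a at -0.122 to 0.043 without 1 array. For sex in mutants, Sox9 stood at 0.015 with normexp, 0.42 with every probe, 0.067 and 0.038 with the array weights, 0.0069 with the covariate and -0.298 to 0.104 without 1 array, and Fgf9 at -0.017 to 0.300 without 1 array. List medians that changed sign with slide as a block were endothelial genes in males (-0.10) and in the difference (-0.077), the bipotential gonad in females (-0.070) and for sex in mutants (0.26), hypoxia response genes in males (-0.01) and erythroid genes for sex in controls (0.46); with the covariate, the bipotential gonad (0.056) and imprinted genes (0.0090) for sex in mutants. Of 71 called gene values 39 lost the call with slide as a block, 27 with only the groups compared, 19 without a filter on dim probes, 17 with the covariate, 14 with normexp, 13 with the replicate block and 5 with the fold threshold. Signal over background limits Sry, Hoxd1 and Tph2 to bounds.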

Other observations

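The genes in these paragraphs were chosen after their values were seen, and so were the lists of muscle, acinar, interferon and germline genes. Some genes of muscle contraction and of pancreatic digestion were among those that fell in both sexes. Of the muscle list 14 of 17 measured members were lower in males and 12 of 17 in females, and of the acinar list 9 of 12 in each, and over these members both lists passed (camera adjusted p = 7.5e-08 and 5.1e-07 for muscle, 3.1e-07 and 7.5e-09 for acinar genes, males and females; adjusted p = 0.00267 for muscle in each sex and 0.0198 and 0.0125 for acinar genes with an estimated correlation). Without the called members neither passed (camera adjusted p = 0.153 and 0.512 for muscle, 0.712 and 0.813 for acinar genes). Among the muscle genes, Tnni3, the cardiac troponin I, fell by 1.57 in males and 1.75 in females, Myl1 by 1.84 and 2.00, and Myl3 by 1.65 and 1.71. Among the acinar genes, Cpa1, a carboxypeptidase, fell by 1.93 and 1.89, and Pnlip, the pancreatic lipase, by 1.20 and 1.24. Of the interferon-response genes, Gbp2 fell by 1.29 and 1.39, Ifi27 by 0.99 and 1.21 and Ifitm2 by 0.79 and 0.73. An unnamed transcript, TC1669112, was at least 26.5-fold lower in males and at least 34.9-fold lower in females.

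For most genes that fell in both sexes, a haplotype carried along with the mutated allele is argued against. Of 35 named genes 1, Capg (2.86%), lay among the 300 nearest genes on each side of Kdm3a on chromosome 6. Only 118 of these neighbours were tested, 0.89% of all named genes tested (Fisher's exact test, one-sided, p = 0.269). On chromosome 6 as a whole lay 4 of the 35, Capg included, and for these a haplotype is not excluded. Slide is argued against by the slide with mutant males and control females, where slide alone would give no difference. There all 39 features without Kdm3a were lower in the mutant males, with a median of -1.29, though that pairing also crosses the sexes. The pairing itself was not compared to choose the features, but its arrays were among those that chose them. Low mutant males and high control females were thus favoured, so the size and count of this fall are not independent of the choice. Within slides of 1 sex the medians were 0.978 times the one over all arrays in females and 1.11 times in males. These ratios decide nothing, since the groups did not overlap in any called feature and each ratio rests on a single array on 1 side. Pancreatic acinar cells in the controls stay open, as the 4 abundant transcripts named beforehand went both ways. Amy2a5 and Prss2 were well above background on no control array, but Cela1 was so on 5 and Ctrb1 on 6 control arrays. Cela1 and Ctrb1 (median -0.144 in males and 0.04 in females) were not called, and their changes decide nothing alone. Heart or skeletal muscle cells in the controls cannot be told apart from genotype, although the 12 muscle members not called met the bound set beforehand against such cells, a median above -0.5 in both sexes (-0.19 and -0.20, with Actc1 at -0.10 and 0.51 against -2.81 and -2.93 for Myl7). That bound was badly set, since members picked for not being called exclude nothing. The same holds for the abundant Actc1, Myh6, Myh7 and Tnnt2 among them (median -0.653 and -0.384). Over all 17 members the median was -0.58 in males and -0.385 in females.

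A fall of the interferon response at large stays open. Over all 25 measured members the median was -0.37 in males (21 lower, camera adjusted p = 2.0e-06; adjusted p = 0.0555 with an estimated correlation) and -0.78 in females (23 lower, camera adjusted p = 3.4e-15; adjusted p = 0.0092 with an estimated correlation). Without the called genes the median was -0.28 in males (camera adjusted p = 0.153; adjusted p = 0.654 with an estimated correlation) and -0.65 in females (camera adjusted p = 3.2e-07; adjusted p = 0.133 with an estimated correlation). A rise of methylation-silenced germline genes at large, as a hypothesis for Gpat2 and Slc25a31, stays open too. Over all 9 measured members the median was 0.31 in males (camera adjusted p = 0.00965; adjusted p = 0.0838 with an estimated correlation) and 0.08 in females (camera adjusted p = 0.0283; adjusted p = 0.125 with an estimated correlation), and without these 2 genes the 7 measured members had a median of -0.05 in males and 0.02 in females (higher camera adjusted p = 0.763), and members went both ways. The bounds set beforehand against both explanations, a list that does not pass without its called genes, were met in males for interferon and in both sexes for germline genes, but they were badly set for the reason given for muscle.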
